A study of Homo sapiens with 5 samples.

How the data were processed

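Total RNA from biopsies of the vastus lateralis, a thigh muscle, had been combined into a pool that the labels call insulin resistant and number 4. The pool was hybridised 1 time to each of 5 Affymetrix oligonucleotide array types, Hu35K subA, subB, subC, subD and HuFL, which carry largely different probe sets. Each array was its own group, so there were no replicates, no test was run and no p-value was computed. No insulin-sensitive muscle was analysed here, so no value describes an effect of insulin resistance.

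The deposited values are signal intensities, 1 per probe set and array, on a linear arbitrary scale, as seen from the values themselves, which are whole numbers that fall below 0 for 23.8% to 32.8% of the probe sets used. The software, background correction and scaling that the authors applied before deposit are not given in the sources used here. The signals were used as deposited, and percentiles were taken within each array because the arrays were not on a common scale. Precision is limited by the number of arrays.

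The 5 arrays held 42843 probe sets, 58 of them control probe sets on each array. GEO's platform annotation, with symbols brought up to date through a RefSeq gene table, gave 1 gene symbol for 29786 probe sets, several for 857 and none for 12200. No gene was named from a probe set with several symbols, and 37 probe sets of sex-linked genes were left unnamed. The named probe sets covered 14427 genes, 6702 of them on more than 1 array. On HuFL, 1062 probe sets (15.0%) were listed at exactly 0, among them abundant muscle transcripts, and these were left out as carrying no estimate. That left 41491 probe sets other than controls.

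The floor of each array was 3 times the root mean square of its negative values, which takes noise as symmetric around 0. A root mean square gives much weight to extreme values, and the lowest HuFL value was -10325, against -2483 to -1272 on the Hu35K arrays. The HuFL floor of 1005 was raised in large part by that value. A robust floor, from the median negative value, was lower on every array, 262 on HuFL. Calls of HuFL signals between 262 and 1005 as below the floor are therefore uncertain. This also holds for 427 to 1006 on subA, 111 to 290 on subB, 111 to 380 on subC and 147 to 399 on subD. A gene's value was the median percentile over its probe sets, and a gene counted as above the floor when at least 50% of its probe sets were. A percentile describes signal, which depends on the binding of each probe as well as on the transcript, so no gene is ranked against another. Each list's median was placed among the medians of 10000 random gene lists of the same size, matched on the number of probe sets (1, 2, or 3 and more) and on presence on HuFL, as a description of these arrays. Intervals of list medians are distribution-free 95% intervals over member genes and do not cover differences between people or pools.

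The 22 gene lists covered fast-twitch and slow-twitch contractile genes, shared sarcomere genes, glycolysis, oxidative phosphorylation, the citrate cycle, fatty acid oxidation, insulin signalling, stress kinases, ribosomal proteins and the proteasome. They also covered markers of erythrocytes, adipocytes, endothelium, fibroblasts, leukocytes, smooth muscle and nerve, and 4 lists of genes typical of other tissues (liver, pancreas, brain and retina, testis and placenta). The named genes were the 4 members of each list with the highest gene value and the 1 with the lowest, 8 and 3 for insulin signalling, the 10 brightest named probe sets of HuFL and the 5 brightest of each Hu35K array. INSR, IRS1, SLC2A4, GYS1, HK2, PIK3R1, AKT2, RRAD and PPARGC1A, and the control probe sets of GAPDH, ACTB and the transferrin receptor, were named wherever measured. An item that this rule also covers is not reported here. These choices, the floor and the alternative settings of the next paragraph were fixed before the data were examined. The treatment of exact zeros, a robust floor, the restriction to probe sets with a plain name suffix and 8 further gene lists were chosen after seeing the data.

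The alternative settings were floors of 2 and 5 times and a floor at the 95th percentile of the off-tissue probe sets, the highest instead of the median probe set, HuFL or the Hu35K arrays alone, random lists from all genes, percentiles among named probe sets, and 2 scalings of the arrays. Each array was also left out in turn for the controls, an offset was added to the control ratios, and the comparison of arrays was repeated on genes above the floor on both.

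The floor was tested on simulated data with noise drawn from each array's negative values and 200 planted probe sets per array. At 3 times the floor 99.5% to 100% of the planted probe sets were called, at 1.5 times 94% to 98.5% and at 0.5 times 1% to 5%, and 0.0861% to 1.38% of the noise was called over these settings. Because this noise shares the symmetry that the floor assumes, the last range is no estimate of false calls in the real data. There, counted by gene and not by probe set, off-tissue genes above the floor were 2 of 18 for liver and 2 of 17 for brain and retina. They were 0 of 9 for pancreas and 0 of 9 for testis and placenta. Of 200 random lists of 20 genes, 3.5% fell outside the central 95% of their random lists. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.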

Results

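Gene expression in human vastus lateralis muscle was measured in 1 pool of total RNA labelled insulin resistant, hybridised 1 time to each of 5 array types. Without replicates or a comparison pool, the data describe which transcripts gave signal in this muscle RNA. Repeated measurement existed only for probe sets shared between arrays. Above the floor were 516 of 8876 probe sets on Hu35K subA (5.81%), 366 of 8866 on subB (4.13%), 447 of 8870 on subC (5.04%), 1013 of 8870 on subD (11.4%) and 434 of 6009 on HuFL (7.22%). By gene, 1240 of 14427 were above the floor.

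The 10 brightest named probe sets on HuFL were those of TNNC1, the troponin C of slow fibres (signal 17812), ATP2A1, the calcium pump of the fast-fibre sarcoplasmic reticulum (16780), TPT1 (15524), MYBPC2 (15413), MYL11 (15090), COX7A1 (14615), TNNT1 (14438), MYH2 (13656), TNNC2 (13632) and RPL39 (12830). On subA they were RPS27 (13705), NDRG2 (11594), NDUFA1 (11478), UQCRQ (11370) and MYL1 (10939). On subB they were CHCHD10 (4616), MYOZ1 (4281), ATP5MC3 (4247), PPP1R3C (3817) and SHISA4 (3642). On subC they were TNNT1 (7602), ANKRD23 (6409), CMYA5 (6203), CASQ1 (6076) and RPS15 (5813). On subD they were RPS20 (10803), HSPB1 (10591), TXNIP (9420), HSPB6 (9402) and RPL41 (9369). These signals are on different scales and are not to be set against each other across arrays.

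The contractile lists asked whether both fibre programmes were present. Of the fast-twitch contractile genes, 11 of 13 were above the floor, with a median percentile of 99.9 (95% interval 96.6 to 99.9). MYL11, a fast myosin light chain, read 15090, MYBPC2, the fast myosin-binding protein, read 15413 on HuFL and 8237 on subD, and CASQ1, the calsequestrin of fast fibres, read 6076 on subC. TPM1 was below the floor in all 4 of its probe sets, at -70 to 177. Of the slow-twitch genes, 7 of 8 were above the floor, with a median percentile of 98.7 (71.5 to 100). MYH7, the slow myosin heavy chain, read 12114, and TNNI1, the slow troponin I, read 8963 on HuFL and 929 on subC. ATP2A2 had 1 of 4 probe sets above the floor, at 8543, while the others read 11 to 149. The fast median lay 1.13 percentile points above the slow one (bootstrap interval over genes -0.65 to 2.38), a difference within the spread of the member genes. Neither list's percentiles give the proportion of fibre types.

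Shared sarcomere and muscle structure genes were above the floor for 17 of 23 members, with a median percentile of 95.1 (75.8 to 98.6). MB, the oxygen-binding myoglobin, read 12442, TCAP, the titin cap, 6616, MYOZ1, a protein of the Z-disc, 9710 on subA and 4281 on subB, and LDB3, also of the Z-disc, 3165 and 3376. CHRNA1, a subunit of the acetylcholine receptor, read 73, below the floor. CKM and ACTA1, chosen after their values were seen, had 1 probe set each, listed at 0 on HuFL, and gave no estimate.

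Energy metabolism formed a further bright block. Glycolysis and glycogen genes were above the floor for 19 of 26 members, with a median percentile of 96.2 (78.4 to 98.8). ALDOA, the muscle aldolase, read 12555, ENO3, the muscle enolase, 10922, and PPP1R3C, which targets a phosphatase to glycogen, 3817. GAPDH had 3 of 4 probe sets above the floor, up to 11667, and PFKFB3 had none of 3, at -195 to 778. Nuclear genes of oxidative phosphorylation were above the floor for 55 of 69 members, with a median percentile of 96.7 (94.8 to 97.9). NDUFA1 of complex I read 11478, UQCRQ of complex III 11370, COX7A1 of complex IV 14615 and ATP5ME of the ATP synthase 8362. NDUFB2 read -6 and 33, below the floor.

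Citrate cycle and pyruvate dehydrogenase genes were above the floor for 10 of 22 members, with a median percentile of 89.4 (71.98 to 95.9). MDH2, the mitochondrial malate dehydrogenase, read 1522 and 4015 in the 2 probe sets above the floor and 460 in the other. GOT1 read 2765, GOT2 read 2580, and SUCLG1 had 2 of 3 probe sets above the floor, up to 1814. PDK3, a kinase of pyruvate dehydrogenase, read -61. Fatty acid uptake and oxidation genes were above the floor for 12 of 28 members, with a median percentile of 86.2 (77.4 to 94.2). ACADM, the medium-chain acyl-CoA dehydrogenase, read 4983, FABP3, the muscle fatty acid-binding protein, 2895, and SLC27A1, a fatty acid transporter, 342. CD36, which takes up fatty acids, was above the floor in all 3 probe sets, at 1154 to 2963. PPARD had no probe set of 3 above the floor, and PPARGC1A, a regulator of mitochondrial genes, had 1 of 3, at 785. With a floor of 5 times the root mean square and one from off-tissue probe sets, 5 and 15 citrate cycle genes and 9 and 19 fatty acid genes were above it. The medians of all 7 lists described so far exceeded those of 100% of their random lists.

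Insulin signalling and glucose uptake genes, the pathway named by the pool's label, were mostly below the floor, as were genes in general. Of 41 measured members 4 were above it, beside 1240 of all 14427 genes. Off-tissue lists had 2 of 18 above the floor for liver and 2 of 17 for brain and retina. Pancreas had 0 of 9, as had testis and placenta. The insulin share lay within that range, so it does not set the list apart from off-tissue genes. The insulin list's median percentile was 66.4 (53.9 to 77.6), above the medians of 99.6% of random lists. That rank was 95.4% on HuFL alone and 95.3% with plain-suffix probe sets. The genes above the floor were IRS2, TBC1D4, a substrate of AKT in glucose transport (1197), GRB10, an adaptor of the insulin receptor (553 and 413 on 2 of 3 arrays), and PEA15 (497 in 1 of 2 probe sets). SLC2A4, the insulin-responsive glucose transporter, read 266, 344 and 828, all below the floor. INSR, the insulin receptor, read -25 to 244 in 6 probe sets, and IRS1, its substrate, -155 to 545 in 5, with no probe set above the floor. PIK3R1 read 1 to 84, AKT2 25 to 507 and HK2, the muscle hexokinase, 0 to 396, and none of these reached the floor. HK2 belongs to the glycolysis and glycogen list, as does GYS1, the muscle glycogen synthase, which was above the floor at 1386. RRAD, a small GTPase of the insulin list, was below it at 801.

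Other members of the insulin list gave GSK3A at 233 and 775, FOXO3 above the floor in 1 of 5 probe sets (1049), PRKAB2 in 1 of 3 (1150) and PRKAG1 at 777. PRKAB1 read -244 to 100, PRKCZ -44 and GRB14 -198 to 34, all below the floor. IRS2, named after its values were seen, had a median percentile of 85.8 over 2 probe sets. The count of 4 depended on the floor, the arrays and the probe sets used. It corresponded to 9.76% of members and became 29.3% at 2 times the root mean square, 43.9% with a floor from off-tissue probe sets and 0% at 5 times. At the same floor it was 0% on HuFL alone, where 1 extreme negative value raised the floor. With each gene's highest probe set it was 9 of 41, and with plain-suffix probe sets 2 of 38.

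Stress kinase and inflammatory genes were above the floor for 2 of 32 members, with a median percentile of 55.6 (37.6 to 68.6), above 74.3% of random lists. That rank was 27.1% with each gene's highest probe set and 95.3% with plain-suffix probe sets. HSPB1, a small heat shock protein, was above it in 2 of 3 probe sets (10591 and 8888) and IKBKB, a kinase of the NF-kappaB pathway, in 1 of 2 (415). NFKBIA read 948 and MAP2K3 read 840, below the floor, and TNFRSF1A, a receptor of tumour necrosis factor, read -280.

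Cytosolic ribosomal protein genes were above the floor for 44 of 55 members, with a median percentile of 96.9 (88.7 to 98.0), above 100% of random lists. RPS27 read 13705, RPL41 9369, RPL30 7571 and RPL39 12830, while RPL28 read -136. On HuFL 37 of 37 ribosomal genes were above the floor, and on the Hu35K arrays 14 of 35. Proteasome genes were above the floor for 7 of 29 members, with a median percentile of 83.4 (73.4 to 89.5), above 100% of random lists. That rank was 90.3% on the Hu35K arrays alone. PSMA4 read 1852 and 2037, PSMB6 2068, PSMC1 1627 and PSMB5 1241, and PSMD5 read -28 and 85. With a floor from off-tissue probe sets the proteasome share was 75.9% instead of 24.1%, and at 5 times the root mean square the count was 3 of 29.

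Lists of markers asked which other cell types the biopsies held. The shares above the floor of the endothelial, fibroblast, smooth muscle, leukocyte and nerve lists, at most 3 of 23 for fibroblasts, were close to the off-tissue range at this floor. That range ran from 0 of 9 for pancreas and 0 of 9 for testis and placenta to 2 of 18 for liver and 2 of 17 for brain and retina. The fibroblast share was slightly above it. With the robust floor, chosen after seeing the data, the counts were 6 of 9 for smooth muscle, 9 of 23 for fibroblasts, 2 of 11 for endothelium, 2 of 15 for leukocytes and 1 of 7 for nerve. Off-tissue counts were then 3 of 18 for liver, 3 of 17 for brain and retina, 2 of 9 for pancreas and 0 of 9 for testis and placenta. Adipocyte markers were above the floor for 4 of 11 members: PLIN1, which coats lipid droplets (2083), ADIPOQ, adiponectin (1639 and 1488), CFD, adipsin (3235 and 2119 in 2 of 3 probe sets), and FABP4 (1827). Their median percentile was 72.9 (40.8 to 96.4), above 96.5% of random lists. That rank was 78.6% on HuFL alone, 91.6% on the Hu35K arrays alone and 98.4% with plain-suffix probe sets. LIPE read -206 to 652. Erythrocyte markers were above the floor for 1 of 5, HBA2, an alpha globin (4168). ALAS2 had 1 of 4 probe sets above the floor (559), EPB42 read 57, SLC4A1 -39 to 154 and AHSP -98 and -26, and the list median was 43.7 (14.4 to 99.9), above 28.0% of random lists. That rank was 17.9% with exact zeros kept, 56.7% with each gene's highest probe set and 71.7% on the Hu35K arrays alone.

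Endothelial markers were above the floor for 1 of 11, VWF (540 in 1 of 2 probe sets), with a median percentile of 67.9 (25.5 to 84.5), above 91.8% of random lists (58.3% on HuFL alone and 40.1% with plain-suffix probe sets). NOS3 read 657, ENG 340, EMCN 71 to 129 and KDR -215. Fibroblast and extracellular matrix markers were above the floor for 3 of 23, LAMC1 (637 in 1 of 2 probe sets) and, named after their values were seen, DCN (median percentile 67.6) and SPARC (55.3), with a median percentile of 55.0 (32.6 to 72.4), above 66.8% of random lists (90.01% on HuFL alone and 16.5% on the Hu35K arrays alone). COL4A1 read 105 and 341, PDGFRA -56 to 331, COL15A1 305 and COL6A1 -149 to -2. Smooth muscle and pericyte markers were above the floor for 0 of 9, although the median percentile was 78.1 (61.1 to 86.8), above 98.0% of random lists. That rank was 85.9% with each gene's highest probe set and 99.2% with exact zeros kept. RGS5, a pericyte marker, had 1 of 6 probe sets above the floor (1770) and MYH11, the smooth muscle myosin, 1 of 3 (1145), while LMOD1 read 579, TAGLN 411 and CNN1 91.

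Leukocyte markers were above the floor for 0 of 15, with a median percentile of 34.5 (13.5 to 43.1), above 3.21% of random lists. LYZ, lysozyme, had 1 of 5 probe sets above it (1196), and CD3E read 925, CD79A 112, GNLY 55 and CD4 -787 to 151. Nerve and Schwann cell markers were above the floor for 0 of 7, with a median percentile of 37.6 (17.3 to 79.8), above 15.4% of random lists. SYP read 217, S100B 110 and 116, NEFH 30 and 68, MBP -10 to 293 and NEFL -74 to 56.

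Genes typical of other tissues gave a check of the floor, beside 1240 of all 14427 genes above it. Shares lower than that of all genes were seen only for pancreas and for testis and placenta at this floor. Liver genes were above it for 2 of 18, F2 (292 in 1 of 2 probe sets) and APOC3 (719 in 1 of 2), with a median percentile of 34.8 (19.5 to 56.1), above 1.04% of random lists. PLG read 184, SERPINA1 -58 to 183 and APOA1 -361 to 56. Pancreas genes were above it for 0 of 9, with a median of 19.8 (3.73 to 73.9), above 1.04% of random lists, and SST read 495, CPB1 283, CPA1 47, PNLIP -8 and CTRB1 -562. Brain and retina genes were above it for 2 of 17, SYN1 (411 in 1 of 2 probe sets) and, named after its values were seen, CAMK2A, with a median of 48.8 (39.7 to 56.1), above 38.2% of random lists, and GRIN1 read 227, SYT1 87 and 343, RBP3 24 and OPN1SW -207. Testis and placenta genes were above it for 0 of 9, with a median of 19.2 (3.17 to 58.3), above 0.545% of random lists. On the Hu35K arrays alone that rank was 19.6%. ZP2 read 161, PSG1 17 to 193, PAPPA -270 to 189, CGA 4 and PRM2 -428.

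**Figure D1:**
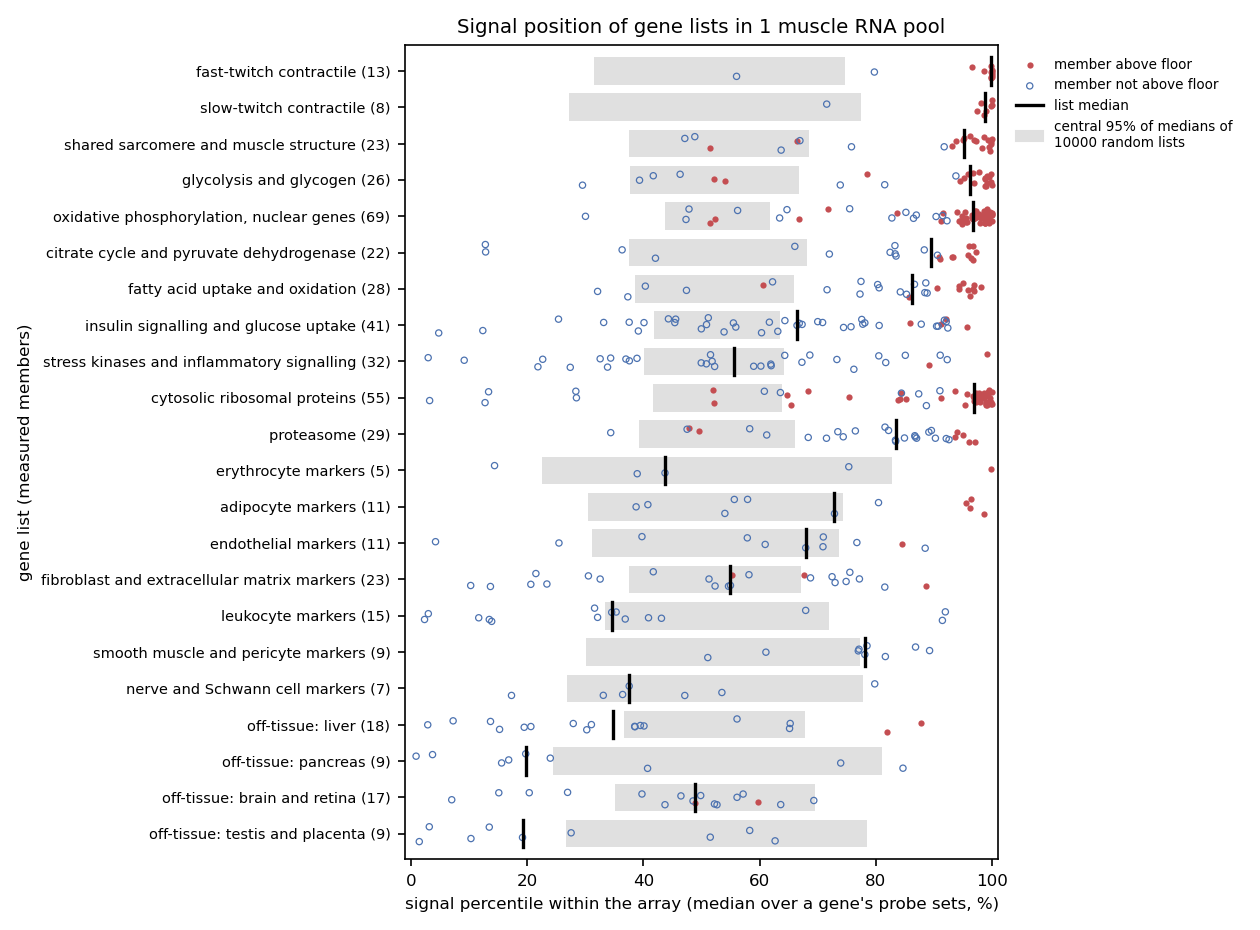
Signal percentile within the array (x axis, %, median over a gene's probe sets) of the members of 22 gene lists (y axis, measured members in parentheses). Filled points are genes above the floor, open points are genes not above it, the black bar is the list median and the grey band holds the central 95% of medians of 10000 random lists. The fast-twitch median was 99.9 and the leukocyte median 34.5.

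The control probe sets measured the same RNA on 5 arrays. GAPDH, a glycolytic enzyme, and ACTB, the cytoplasmic beta actin, were above the floor on all 5 arrays in their 3', middle and 5' probe sets, 6 of the 19 human control probe sets. The GAPDH 5' probe set read 17418 on subA, 5268 on subB, 7106 on subC, 10531 on subD and 16801 on HuFL, with a mean of 11425 ± 5527 (SD, n = 5 arrays of 1 pool). The ACTB 5' probe set averaged 6359 ± 2704 and the ACTB 3' probe set 1692 ± 870. Transferrin receptor probe sets read -15 to 180 and were above the floor on no array.

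The coefficient of variation of the 6 bright control probe sets between arrays had a median of 47.1% (39.3% to 51.4%). After each array was multiplied by 1 factor to bring these probe sets to HuFL, 0.821 for subA, 2.54 for subB, 2.03 for subC and 1.27 for subD, it was 9.53% (3.64% to 18.0%). The control probe sets of bioC, bioD and cre, which come from bacteria and a phage and did not enter the factor, went from a median of 39.1% to 13.4% over the 5 that were above the floor on all arrays. Bacillus subtilis control probe sets gave 0 of 75 readings above the floor. The 3' to 5' signal ratio was 0.680 ± 0.0279 for GAPDH and 0.262 ± 0.0427 for ACTB (SD, n = 5 arrays of 1 pool). These ratios compare different probe sets, so their distance from 1 also holds the probes' binding.

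**Figure D2:**
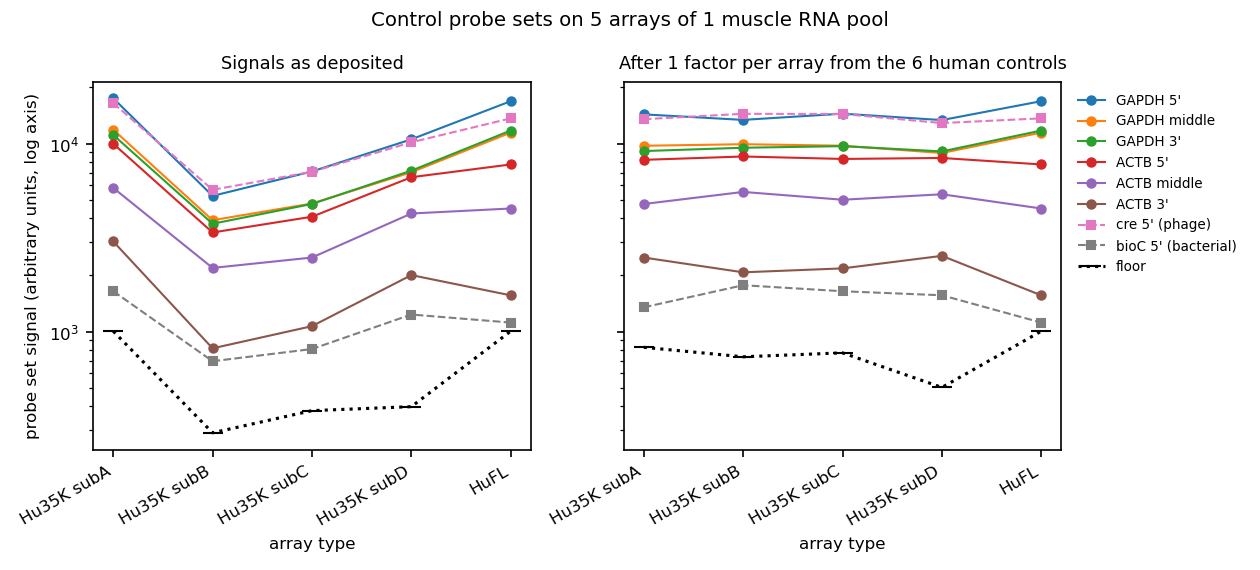
Signals of GAPDH, ACTB, cre and bioC control probe sets (y axis, arbitrary units, log axis) on the 5 array types (x axis), as deposited on the left and after 1 factor per array on the right. Each point is 1 probe set on 1 array, dashed lines are the phage and bacterial controls and the dotted line is the floor. The median coefficient of variation of the 6 human controls was 47.1% on the left and 9.53% on the right.

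Genes with probe sets on 2 arrays gave weakly related signals. Probe sets with the same name on both arrays were not taken out of this comparison. Across genes, which are not independent replicates, Spearman's correlation of floored signals lay between 0.137 (subB and subC, 1185 genes) and 0.355 (subC and HuFL, 1034 genes) over the 10 pairs of arrays. The number of genes above the floor on both arrays was 46 of 1820 for subA and subD, against 14.2 if the calls were independent, and 8 of 623 for subB and HuFL, against 0.978. Among genes above the floor on both, the median absolute log2 difference of the signals as deposited was 0.52 to 1.23. SubA and HuFL shared 405 probe set names, with a Spearman's correlation of 0.364 for signals that were not floored. Without the floor it was 0.225 across the 1032 genes measured on these 2 arrays. Of the 405 names 5 were above the floor on both arrays, 7 on subA only and 3 on HuFL only. CFD, above it on both, read 3235 on subA and 2119 on HuFL. A same-named probe set of SLC2A4 read 266 on subA and 828 on HuFL, and 1 of LIPE 652 and -206, all below the floor. The spread of the log2 differences of the 5 selected as above the floor on both corresponded to a 1.29-fold error of a single signal.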

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

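The tests of the exact zeros, of the brightness factor, of the scaled floors and of the ribosomal gap with plain-suffix probe sets were chosen only after the results they measure, or closely related values, had been seen. No biological explanation was tested for these patterns, since all arrays held the same RNA.

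A probe set for the sense strand of the 3' part of ACTB gave signal on all 5 arrays, above each floor, at 1925, 769, 865, 1363 and 1567. It drew attention because it lies outside the measured transcripts and the other 14 sense-strand control probe sets gave no reading above the floor. Its ratio to the antisense partner was 0.816 ± 0.159 (SD, n = 5 arrays of 1 pool), while that of GAPDH was 0.0333 ± 0.00467.

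A probe set for the Alu repeat, which has no gene name, was above the floor on all 5 arrays, with a mean signal of 8593 ± 4205 (SD, n = 5) and a coefficient of variation of 14.9% after the control factor. Probe sets with no gene name here gave 425 signals above the floor, 45 on subA, 53 on subB, 78 on subC, 168 on subD and 81 on HuFL. No gene list held them, though they entered the percentiles within each array and the counts per array.

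CKM, ACTA1, CA3 and HBB, abundant in muscle or blood, were among the HuFL probe sets listed at exactly 0. If low signals had been set to 0, the genes concerned would lie low on the Hu35K arrays. The 331 genes whose HuFL values were all 0 and that had a Hu35K probe set had a median percentile there of 52.4, against 53.7 for 2399 genes with nonzero values, a difference of -1.32 (bootstrap interval -5.38 to 4.58), which argues against this. They lay 7.97 percentile points (3.46 to 14.97) above the 566 genes with negative HuFL values. A missing or masked estimate remains open as an untested hypothesis.

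Human control signals were 3.09 times as high on subA as on subB by the geometric mean of the 6 bright probe sets, and single probe sets differed by more or less than that. A single brightness factor per array may account for this, since it brought the bacterial and phage controls, which did not set it, to a median coefficient of variation of 13.4%. The trimmed means of all other probe sets gave a factor of 7.32 for subB, against 2.54 from the controls. The reason for that gap, and whether the factor arose in hybridisation, scanning or the authors' scaling, were not tested.

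Ribosomal protein genes stood at the top of the signal range on HuFL (37 of 37 above the floor, exact zeros left out) and less so on the Hu35K arrays (14 of 35). Different genes on the arrays do not account for the gap: among 17 genes on both, 17 were above the floor on HuFL and 4 on the Hu35K arrays, a gap of 76.5 percentage points (52.9 to 94.1). Probe sets shared between related genes are argued against as well, since plain-suffix probe sets alone kept the list's median at 96.2, above the random range of 40.6 to 63.5, and gave a gap of 90.9 points. A higher floor is argued against, since the highest Hu35K floor was 825 on the HuFL scale of the controls, against 1005 for HuFL, and although the trimmed means put it at up to 2120 (subB), floors made equal on that scale left the gap among the shared genes at 76.5 points (58.8 to 94.1). Probe sets of the Hu35K arrays that lie in poorly binding or absent parts of these transcripts remain a candidate explanation, which was not tested. Such a gap was not confined to ribosomal genes. With plain-suffix probe sets, of 9 oxidative phosphorylation genes on both, 8 were above the floor on HuFL and 2 on the Hu35K arrays (66.7 points, 33.3 to 100). With all probe sets that gap was 5.88 points (-29.4 to 41.2). Several lists went the other way with plain suffixes, among them the citrate cycle (-16.7 points, -50 to 0).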

How the results depend on the processing

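The robust floor, the plain-suffix probe sets and the keeping of exact zeros were chosen after seeing the data. Of 584 values under alternatives, 491 stayed within their interval or tolerance, 91 moved beyond it and 2 changed sign. Some of the 491 could not move by construction. Scaling signals and floors together leaves Spearman's correlation as it was, and keeping exact zeros leaves the counts per array as they were. Shares were judged against intervals that are wide for short lists, so the tally is no measure of stability. The cause was not tested unless the alternative's construction shows it. Signal over background set the limit: a lower floor can raise a count and cannot lower it. At 2 times the root mean square the fast-twitch, slow-twitch, adipocyte and endothelial counts stayed at 11, 7, 4 and 1. The adipocyte and endothelial counts were 5 and 2 with the off-tissue floor and 7 and 2 with the robust floor.

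At 2 times the root mean square 944 probe sets were above the floor on subA, 632 on subB, 782 on subC and 680 on HuFL, 29.3% of insulin signalling genes and 48.3% of proteasome genes. At 5 times the counts were 224, 161 and 237 on subA, subB and subC and 588 on subD, with 22.7% of citrate cycle genes and 0% of insulin signalling, endothelial and brain and retina genes. With the off-tissue floor they were 1380, 937 and 1536 on subA, subB and subC and 1588 on HuFL, while on subD, where that floor is higher (521 against 399), the count fell from 1013 to 753. The shares were then 68.2% for the citrate cycle, 67.9% for fatty acid oxidation, 43.9% for insulin signalling, 28.1% for stress kinases, 75.9% for the proteasome and 66.7% for smooth muscle. The robust floor gave 1642, 1233, 1781 and 2413 on subA to subD and 1653 on HuFL. Its shares were 77.3% for the citrate cycle, 75% for fatty acid oxidation, 48.8% for insulin signalling, 31.2% for stress kinases, 75.9% for the proteasome, 39.1% for fibroblasts and 66.7% for smooth muscle.

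Taking each gene's highest probe set, which raises values by construction, gave 100% above the floor for slow-twitch genes and 89.9% for oxidative phosphorylation. Median percentiles were then 98.7 for oxidative phosphorylation, 87.7 for insulin signalling, 68.7 for stress kinases, 98.9 for ribosomal proteins, 89.7 for the proteasome, 75.5 for fibroblasts and 57.2 for brain and retina.

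On HuFL alone, ribosomal proteins reached 100% and a median of 98.8, and insulin signalling, erythrocyte, endothelial, liver and brain and retina genes 0%. On the Hu35K arrays alone, ribosomal proteins fell to 40% and a median of 71.3, and the proteasome median was 64.1. Plain-suffix probe sets gave 100% for slow-twitch, 52.2% for glycolysis and 0% for endothelial genes. Ranks among random lists varied widely for the lists near the middle and also moved for lists at the low and high ends. The proteasome went from 100% to 90.3% on the Hu35K arrays alone, and adipocyte markers from 96.5% to 78.6% on HuFL alone. Smooth muscle went from 98.0% to 85.9% with the highest probe set, and insulin signalling from 99.6% to 95.3% with plain suffixes. On the Hu35K arrays erythrocyte markers went from 28.0% to 71.7%, nerve from 15.4% to 44.5% and testis and placenta from 0.545% to 19.6%. On HuFL alone pancreas genes went from 1.04% to 12.6% and leukocyte markers from 3.21% to 20.4%. Brain and retina genes went from 38.2% to 12.6% with the highest probe set. Stress kinases went from 74.3% to 27.1% with the highest probe set and 95.3% with plain suffixes, endothelial markers from 91.8% to 40.1% with plain suffixes, and fibroblasts from 66.8% to 16.5% on the Hu35K arrays. The fast minus slow difference stayed positive, at 0.158 to 2.08 percentile points.

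The median coefficient of variation of the controls was 38.9% after scaling to the trimmed mean, 9.53% after scaling to the human controls, and 38.2% to 53.0% with 1 array left out. The 3' to 5' ratios stayed at 0.672 to 0.691 for GAPDH and 0.252 to 0.277 for ACTB with 1 array left out.

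With genes above the floor on both arrays only, which leaves 8 to 46 genes, Spearman's correlation changed sign for subB with subD (-0.114) and subB with HuFL (-0.0952). For subA it was 0.339 with subB, 0.577 with subC, 0.311 with subD and 0.371 with HuFL. It was 0.55 for subB with subC, 0.394 for subC with subD, 0.602 for subC with HuFL and 0.683 for subD with HuFL. Scaling to the trimmed mean moved the median absolute log2 difference of subC and subD from 0.59 to 0.90.

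No paired analysis was possible because each group held 1 hybridisation and the result comes from no test.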

Other observations

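The 8 gene lists below were chosen after the data had been seen and before their values were computed, and some of their genes also stand in the lists of the report. Calcium handling and excitation-contraction coupling genes were above the floor for 12 of 22 members, with a median percentile of 93.1 (66.9 to 97.4). SLN, sarcolipin, which inhibits the calcium pump, read 12584, and SRL, sarcalumenin of the sarcoplasmic reticulum, read 2091, beside ATP2A1 and CASQ1. Energy transfer and mitochondrial carrier genes were above the floor for 9 of 14, with a median of 95.9 (83.5 to 98.7). AMPD1, the muscle AMP deaminase, read 4539 and 2128, VDAC3 1882 and 2774, and SLC25A3, the phosphate carrier, 5611. Heat shock and antioxidant genes were above the floor for 19 of 27, with a median of 95.3 (88.1 to 97.7). CRYAB, the small heat shock protein alpha B-crystallin, read 9244, HSPB8 985 and MT1X, a metallothionein, 1333 and 1319 in 2 of 3 probe sets.

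Of the respiratory chain, complexes I, III and IV and the ATP synthase were taken as lists, and complex II was not. Their genes stand in the oxidative phosphorylation list above, so their positions restate that result by complex and are no separate evidence. Complex I genes were above the floor for 23 of 29 (median percentile 97.3, interval 92.2 to 99.2), with NDUFC1 at 5053, NDUFS6 at 1049 and NDUFB9 at 4070 and 3717. Complex III genes were above it for 5 of 7 (94.8, 63.4 to 99.9), with UQCRC1 at 3174, CYC1 at 1840 and UQCRC2 at 1525. Complex IV genes were above it for 11 of 12 (97.6, 71.7 to 98.7), with COX6A2, a muscle isoform, at 8881 and 6482, COX7C at 6706 and COX6B1 at 4205 and 2197. ATP synthase genes were above it for 13 of 15 (97.2, 94.4 to 98.7), with ATP5F1A at 8537, ATP5F1E at 5216 and ATP5MF at 2611. Complement and acute phase genes were above it for 3 of 15 (80.0, 61.7 to 91.2): APOD in all 4 probe sets at 889 to 3937, CFD, and CLU at 930 in 1 of 2, while C1S read 858. The medians of these lists exceeded those of 100% of random lists, and of 99.8% for complement.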
